A study of Mus musculus with 2 samples.

How the data were processed

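Total RNA was taken from the left cerebral cortex of 14-day-old female B6CASTF1/J mice with a column kit for animal tissue, depleted of ribosomal RNA and sequenced with strand information and ERCC spike-ins, per the labels. The labels give 2 biological replicates with separate tissue samples and the same donor entry. The description of both speaks of 3 females, the tissue label of replicate 1 does so too with a number and that of replicate 2 names a female with another number, and whether a library pools mice is not given in the sources used here. Both belong to 1 group, and replicate numbers are those of the labels. As the labels call them biological replicates and their counts differed by more than sampling noise, they were counted as 2 samples. Such a difference does not by itself show that they come from different mice.

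For each library the authors deposited a gene table and a transcript table, both quantified from a transcriptome alignment, and a second transcript table quantified from the reads, on assembly mm10 with GENCODE M21 annotation, per the text files deposited with the samples. The tools and their settings are not given in the sources used here. Expected counts in the gene and transcript tables are estimated reads per feature and are not normalised, per the file headers and the deposited values. Estimated counts in the second transcript table are of the same kind, per the file headers. TPM values in all tables were scaled by the authors to the same total over all rows of a table, spike-ins included, so that a few abundant short RNAs lower the TPM of every other gene. The difference between length and effective length was 99 nucleotides in the deposited first tables and 341 and 347 nucleotides in the second table of replicate 1 and replicate 2, so that the tables assume different fragment lengths. Strand settings of the counting are not given, so levels of overlapping antisense genes are uncertain.

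All 55536 gene identifiers matched the GENCODE M21 annotation, which gave symbols, biotypes and mm10 coordinates, and 55450 had transcripts in the second table, where TPM and estimated counts were summed per gene. A further 26248 numbered rows of 61 to 259 nucleotides that name no gene, 96 ERCC rows and 1 other spike-in row were left out of gene totals and tests. The numbered rows held 5 and 4.84 counts, 1.49e-05% and 1.51e-05% of the totals. Where a symbol had several identifiers (115 symbols), its values were summed for list levels and pairs, and the difference between libraries was given only for symbols with 1 tested identifier.

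A gene was called detected at 1 TPM or more in both libraries. Lists of markers and functions, 26 gene pairs and 16 genes for transcript shares were fixed before the data were examined. Pairs were compared as log2 ratios of (TPM + 0.1) within each library with limma 3.58.1 (intercept only, empirical Bayes, Benjamini-Hochberg over the pairs, R 4.3.3). With 2 libraries an exact test cannot go below p = 0.5. The estimated prior degrees of freedom were infinite, so the pairs share 1 pooled variance, and p-values of pairs with a wider spread, such as Mog over Pdgfra, rest on that assumption. On simulated data with 13 of 26 pairs changed, 94.0% of pairs with a log2 ratio of 1 were called and 4.15% of the unchanged ones. TPM ratios between genes also depend on the effective lengths that the authors' tables assume.

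The libraries were compared per gene with a two-sided exact binomial test on rounded expected counts, with the expected share from edgeR 4.0.16 TMM library sizes (0.500 for replicate 2), for the 18887 genes with 10 counts or more in at least 1 library, adjusted by Benjamini-Hochberg. This takes counting error alone and says nothing about other mice. CPM stands for counts per 1e6 gene counts. Ratios were computed as log2 of (CPM + 0.5), which understates the change of low genes. Errors of log2 ratios are counting SEs, computed from the counts without the added 0.5. For low genes they are therefore not the errors of the ratios shown. Data were simulated with counting error alone, the error that the test assumes, from the same 18887 genes with 200 changed. The test called 66.0%, 78.0%, 90.0% and 92.0% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, and 8 of 18687 unchanged genes. With a wider spread between libraries that rate of false calls does not carry over. List medians were set against 10000 random lists, each drawn within 100 genes of the members' ranks of mean expression. In a single simulation of independent genes, a list of 12 genes shifted down by nearly as much as the myelinating oligodendrocyte list lay at percentile 0. An unshifted list lay at 3.09. A single draw does not measure how often smaller shifts are found or unshifted lists fall outside. Lists with fewer than 3 tested genes (hypothalamus and pituitary, Y-linked) were left out of that comparison. Cspg4, Igf2, Meg3 and Kcnq1ot1 stand in 2 lists each. The common dispersion came from edgeR with an intercept only.

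The tables of a library were compared as log2 ratios of (TPM + 0.1). Transcript shares are shares of the gene's summed TPM. Genes named in the text follow a rule fixed beforehand: the 10 highest nuclear protein-coding genes, 5 mitochondrial genes and 10 of other biotypes; the 3 highest members of each list; the members of all pairs and the isoform genes; the 10 genes with the largest ratio between libraries in each direction among those called with 100 or more counts on average and the same direction in both quantifications; and the 5 most different genes in each direction between quantifications at 10 TPM or more. Other list members given as examples of the difference between libraries were chosen after their values were seen. Summaries and figures name fewer genes than the rule allows, and results of some genes are not reported here.

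Alternatives fixed beforehand were other detection thresholds (0.5 and 5 TPM), TPM rescaled to nuclear protein-coding genes, pseudocounts of 1 and 0.01 TPM, the other quantification, DESeq2 1.42.0 size factors, total counts or ERCC totals in place of TMM, no filter beyond 1 count, an edgeR exact test with a preset dispersion of 0.01, and each library alone. Rescaling both tables for their comparison was added after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used otherwise. ERCC rows with known amounts were not used for absolute quantities, and alleles of the parent strains were not analysed here.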

Results

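Total RNA depleted of ribosomal RNA was sequenced from the left cerebral cortex of 14-day-old female B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST/EiJ strains. The data hold 2 libraries of 1 group, called biological replicates in the labels and each made from 300 ng of RNA with added ERCC spike-ins, which are synthetic transcripts of known amount. There was no second condition, so the design allows levels within this tissue, comparisons between genes of the same library, and the difference between the 2 libraries. The description shared by both libraries speaks of 3 females, while the tissue labels differ: that of replicate 1 speaks of 3 females and carries a number, and that of replicate 2 speaks of a female and carries another. How many mice each library holds is not known. Genes received 33.4M expected counts in replicate 1 and 32.0M in replicate 2. Spike-ins took 0.360% ± 0.00118 of all counts (SD, n = 2), with 64 and 62 of the 96 spike-ins at 1 count or more. Intervals and errors from counts cover counting error only.

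The first question was which genes the tissue expressed. Of 55536 annotated genes, 14757 reached 1 TPM in both libraries, and 12959 of these were protein-coding. Among nuclear protein-coding genes the highest levels belonged to Actb, cytoplasmic beta-actin, at 1449 ± 29.3 TPM (SD, n = 2), Nrgn, a calmodulin-binding protein of dendrites, at 1345 ± 95.8 TPM, and Eef1a1, a translation elongation factor, at 1322 ± 16.5 TPM. Snurf followed at 1281 ± 16.1 TPM, but its annotated transcript of 216 nucleotides lies within the Snrpn locus on chromosome 7 (59995449 to 60005049), and its level was 0 in the other quantification. Also among the highest were Calm2 (1159 ± 45.6 TPM), Cpe, which trims neuropeptide precursors (1129 ± 42.4 TPM), Syp, a synaptic vesicle protein (1116 ± 9.93 TPM) and Gapdh (1111 ± 50.7 TPM). The order depends on the quantification: in the other one Gapdh (3732 ± 86.8 TPM) stood above Actb (2731 ± 104 TPM). Mitochondrial genes took 7.44% of gene counts in replicate 1 and 6.62% in replicate 2, most of it in the ribosomal RNAs mt-Rnr2 (42601 ± 3323 TPM) and mt-Rnr1 (26375 ± 2395 TPM). By assigned reads, mt-Co1 was the highest mitochondrial messenger at 5830 ± 415 TPM. It was followed by mt-Cytb at 3074 ± 251 TPM and mt-Nd1 at 2991 ± 255 TPM. Reads shared with the mitochondrial-like pseudogenes of chromosome 1 named below could change this order and the mitochondrial share of counts.

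Outside the protein-coding genes, short structural RNAs dominated the TPM scale. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle on chromosome 12, stood at 130745 ± 2204 TPM each (SD, n = 2). Their sequences are identical, so the even division between them came from the counting. Rn7sk, the RNA that holds back the elongation factor P-TEFb, was at 43559 ± 1219 TPM, and Rpph1, the RNA of ribonuclease P, at 8269 ± 231 TPM. The class of misc_RNA, which holds the first 3 of these, made up 30.5% ± 0.569 of TPM but only 4.03% ± 0.0693 of gene counts. Malat1, a nuclear long noncoding RNA, stood at 3177 ± 560 TPM. Gm26917 on chromosome 17, at 14941 ± 282 TPM, and the unprocessed pseudogenes Gm28661, Gm10925 and Gm28437 on chromosome 1, between 4117 and 6650 TPM, were also among the 10 highest. Those 3 pseudogenes lie side by side at 24613189 to 24615565, and their levels are uncertain where they share reads with near-identical copies.

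The second question was which cell types and regions the tissue's RNA represented, read from 25 marker lists and 12 functional lists fixed before the data were examined. Of 358 list memberships, 303 were at 1 TPM or more in both libraries, and 22 of the 37 lists had every member at that level. Excitatory neuron genes had a median of 51.8 ± 2.04 TPM (SD of the library medians, n = 2), led by Nrgn, Camk2a, a postsynaptic kinase (891 ± 36.0 TPM), and Slc17a7, the main cortical vesicular glutamate transporter (757 ± 20.2 TPM). Inhibitory interneuron genes had a median of 34.1 ± 0.951 TPM, with high levels of the neuropeptide Sst (212 ± 4.92 TPM) and the GABA-synthesising enzyme Gad1 (109 ± 2.33 TPM). Astrocyte genes had a median of 60.3 ± 2.83 TPM, with high levels of the glutamate transporter Slc1a2 (1066 ± 85.3 TPM) and of Aldoc (261 ± 13.1 TPM). The layer 2 to 4 list had a median of 57.9 ± 0.467 TPM, with Cux2 highest. The layer 5 list had a median of 20.7 TPM in each library, with Crym at 74.1 ± 4.04 TPM, and the layer 6 and 6b list 12.3 ± 2.46 TPM, with Rprm at 65.7 ± 3.17 TPM.

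Precursor, microglial and vascular genes had lower medians than the astrocyte, myelin, excitatory neuron and interneuron lists. Myelinating oligodendrocyte genes had a median of 61.8 ± 23.2 TPM (SD, n = 2), a spread larger than that of any neuronal list. The oligodendrocyte precursor list stood at 15.8 ± 0.233 TPM, led by the transcription factor Olig1 (63.0 ± 6.65 TPM). Microglia genes had a median of 17.1 ± 0.156 TPM, among them P2ry12 (35.0 ± 2.23 TPM) and Csf1r (33.8 ± 1.03 TPM). The tight-junction gene Cldn5 led the endothelial list (40.7 ± 0.594 TPM), Rgs5 the mural list (46.9 ± 0.643 TPM) and Igf2 the meningeal and perivascular fibroblast list (77.9 ± 9.90 TPM). Haemoglobin genes were high, with Hbb-bs at 365 ± 94.1 TPM and Hba-a1 at 328 ± 114 TPM.

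Markers of other tissue were low or absent for most regions. Striatal genes had a median of 20.6 ± 5.93 TPM (SD, n = 2), led by Ppp1r1b, the dopamine signalling protein DARPP-32, at 87.5 ± 34.8 TPM. Hippocampal and thalamic lists had medians of 4.14 ± 0.283 and 3.37 ± 0.332 TPM. Choroid plexus, ependymal, cerebellum and olfactory bulb, hypothalamus and pituitary, peripheral leukocyte, and muscle and bone lists all had medians under 1 TPM as the mean of the libraries. Choroid plexus (0.535 and 1.25 TPM), ependymal (1.22 and 0.650 TPM) and cerebellum and olfactory bulb (0.655 and 1.02 TPM) exceeded it in 1 library. Proliferating cell genes had a median of 1.19 ± 0.0707 TPM, with none of the 8 above 2.63 TPM. Xist, which is transcribed from the inactive X chromosome of females, was at 71.9 ± 10.4 TPM. The 4 Y-linked genes together received 0 counts in replicate 1, which allows up to 0.0899 CPM, and 4 counts in replicate 2.

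**Figure D1:**
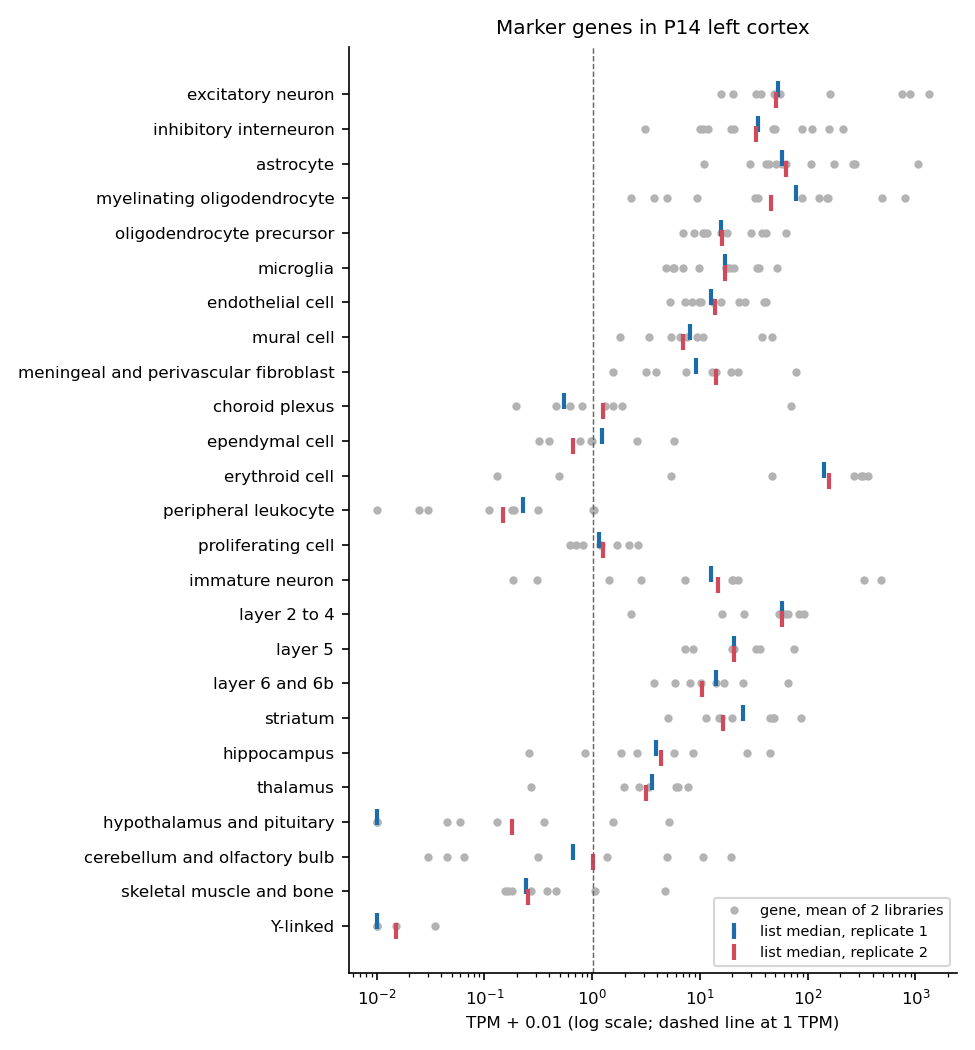
Each grey point is 1 marker gene at its mean TPM over 2 libraries, and the coloured bars are the list medians per library, on a log axis of TPM + 0.01. Excitatory neuron and astrocyte medians lie above 50 TPM, Y-linked genes lie at the left edge, and the myelinating oligodendrocyte medians of the libraries stand apart.

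Synaptic genes were among the highest functional lists. The synaptic vesicle and release list had a median of 304 ± 0.240 TPM (SD, n = 2), led by Syp, Snap25 (809 ± 47.6 TPM) and Vamp2 (581 ± 4.77 TPM). Postsynaptic scaffold genes had a median of 135 ± 0.460 TPM, among them Dlg4 (484 ± 15.2 TPM) and Shank1 (248 ± 8.82 TPM). Glutamate receptor genes had a median of 87.3 ± 1.64 TPM, with the NMDA receptor subunit Grin1 at 229 ± 4.55 TPM and the AMPA receptor subunit Gria2 at 214 ± 16.0 TPM. The GABA-A receptor list had a median of 46.9 ± 1.49 TPM. Voltage-gated channel genes had a median of 49.1 ± 3.72 TPM, led by Scn2a (158 ± 4.82 TPM) and Cacna1a (135 ± 1.63 TPM). Of the perineuronal net and matrix genes, Ncan (165 ± 2.57 TPM) and Bcan (153 ± 4.77 TPM) were high, while the aggrecan gene Acan was at 1.32 ± 0.00707 TPM. Immediate early genes had a median of 14.5 ± 0.619 TPM, with the activity-induced factor Egr1 at 73.5 ± 2.60 TPM. The stress response list was led by Tsc22d3 (46.7 ± 8.57 TPM), a glucocorticoid target, and the heat shock and hypoxia list by Hsph1 (126 ± 9.87 TPM).

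The third question was which member of a gene family or of a developmental pair was higher within a library. Of 26 preset pairs, 24 differed at an adjusted p under 0.05 in limma's moderated test, 19 with the first gene higher and 5 with the second. Slc17a7 exceeded Slc17a6, the vesicular transporter of subcortical neurons, 48.1-fold (mean log2 ratio 5.59 ± 0.22 SD, n = 2, limma adjusted p = 7.63e-24). Slc12a5, which extrudes chloride from mature neurons, exceeded the chloride importer Slc12a2 12.5-fold (3.64 ± 0.15, limma adjusted p = 1.34e-19). The NMDA subunit Grin2a was still below the early-life subunit Grin2b, which stood 1.60-fold higher (log2 ratio -0.67 ± 0.08, limma adjusted p = 4.19e-05). Among sodium channels Scn2a exceeded Scn1a 4.04-fold (-2.02 ± 0.05), while Scn8a exceeded the embryonic Scn3a 5.09-fold (2.35 ± 0.29). The interneuron peptide Sst exceeded Pvalb 10.3-fold (-3.37 ± 0.24) and Vip 10.7-fold (3.42 ± 0.04).

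Other pairs set mature against immature or neuronal against glial forms. Mapt, the microtubule protein tau, exceeded Dcx, a marker of migrating neurons, 6.87-fold (mean log2 ratio 2.78 ± 0.31 SD, n = 2). Nefl exceeded the late-appearing neurofilament Nefh 9.60-fold (-3.26 ± 0.09). Bcan exceeded Vcan 12.1-fold (3.60 ± 0.31), and the de novo DNA methyltransferase Dnmt3a exceeded Dnmt1 8.29-fold (3.05 ± 0.15). Ratios were smaller for Gad1 over Gad2 (1.14 ± 0.08), Gria2 over Gria1 (1.04 ± 0.12), Camk2a over Camk2b (1.28 ± 0.05), Eno2 over Eno1 (1.02 ± 0.02) and Ldhb over Ldha (0.53 ± 0.08). In the other quantification Ldhb over Ldha was 1.25, Gad1 over Gad2 0.65, Slc1a2 over Slc1a3 2.11, Bcan over Vcan 4.08 and Grin2a over Grin2b -0.33, all still with limma adjusted p under 0.05. Vamp2 exceeded Vamp1 25.5-fold, Dlg4 exceeded Dlg3 6.75-fold and Slc1a2 exceeded Slc1a3 6.11-fold. Kcna2 over Kcna1 (0.37 ± 0.06, limma adjusted p = 0.0131) and Gfap over Aqp4 (0.31 ± 0.04, limma adjusted p = 0.032) passed here but not in the other quantification, where the log2 ratios were 0.09 and 0.14. Syn1 over Syn2 (0.24 ± 0.11, limma adjusted p = 0.0934) did not pass, nor did Mog over Pdgfra (0.05 ± 0.59, limma adjusted p = 0.739), where the sign differed between the libraries. The estimated spread was pooled fully over the pairs, so each has the same SE of 0.135.

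**Figure D2:**
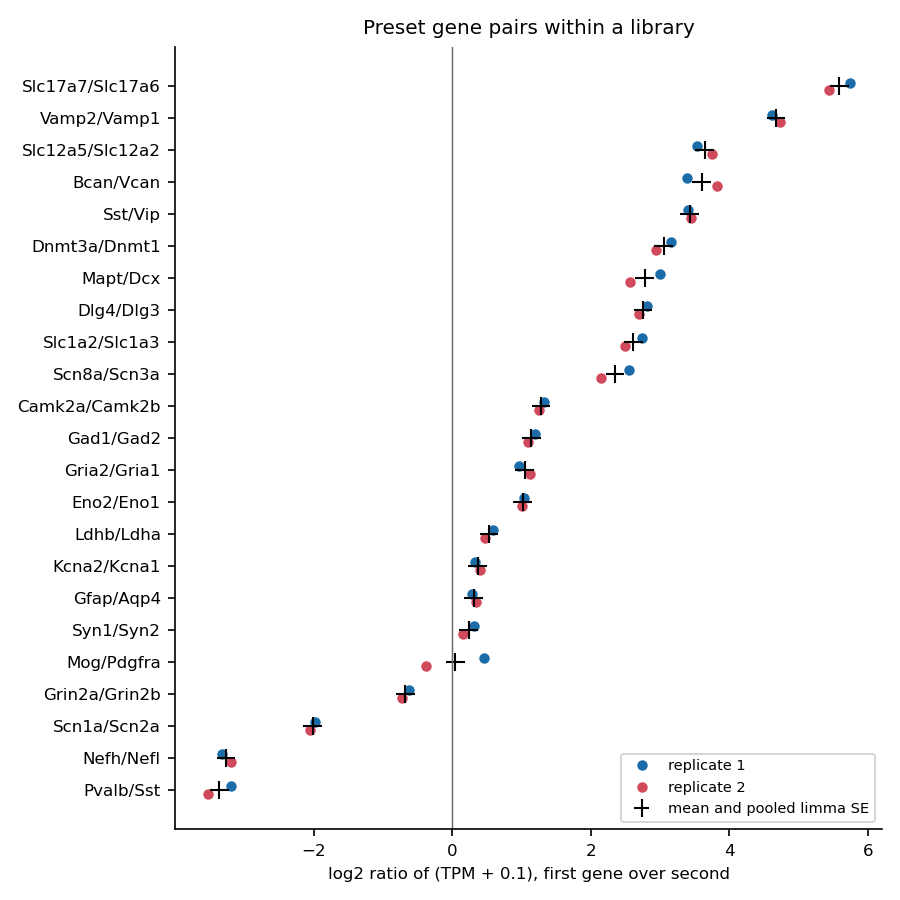
Points give the log2 ratio of (TPM + 0.1) of preset gene pairs in replicate 1 and replicate 2, with the mean and the pooled SE in black. The replicates lie furthest apart for Mog over Pdgfra, at 0.47 and -0.37. Mapt over Dcx, at 3.00 and 2.56, and Bcan over Vcan, at 3.38 and 3.82, come next.

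The fourth question was how far the 2 libraries differed. The libraries were alike across genes (Spearman rho 0.993 across 18887 genes, which are not independent replicates), with a common biological coefficient of variation of 0.0883. An exact binomial test, which compares these libraries and not conditions, called 3738 of the 18887 genes at an adjusted p under 0.05, 1612 higher and 2126 lower in replicate 2. Of these, 123 differed 2-fold or more, 71 higher and 52 lower. Scaling by total counts gave 2692 higher and 1135 lower, and scaling by spike-ins 2517 higher and 1211 lower. With an assumed dispersion of 0.01 in place of counting error alone, edgeR called 182 genes, 100 higher and 82 lower. Of 35 lists with 3 or more tested genes, 17 had a median outside the central 95% of random lists matched on expression, where 1.75 would be expected for lists of independent genes. Of these, 7 lay above their range and 10 below.

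Myelin genes were lower in replicate 2. Of the 12 myelinating oligodendrocyte genes, 11 were called lower in the exact binomial test and none higher, also 11 adjusted over the list alone, with a median log2 ratio of -0.85 (SD over genes 0.18) below all 10000 random lists. Mbp, myelin basic protein (chromosome 18, 82475146 to 82585637), fell from 1014 TPM in replicate 1 to 575 TPM in replicate 2, a log2 ratio of -0.86 ± 0.01 (counting SE). Mog, a glycoprotein of the myelin surface, was at 42.7 and 21.8 TPM (exact binomial adjusted p = 1.76e-54). Aspa, with 76 and 57 counts, was not called (-0.33 ± 0.25). The precursor list moved less: 7 of 11 genes were called lower, also 7 adjusted over the list alone, with a median of -0.16. Its larger ratios were those of Enpp6 (-0.58 ± 0.08) and Bcas1 (-0.40), genes of differentiating oligodendrocytes, while Pdgfra was at -0.16 ± 0.04.

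Striatal genes were also lower in replicate 2. Of 9, 8 were called lower in the exact binomial test and 8 adjusted over the list alone, with a median log2 ratio of -0.61 (SD over genes 0.37), below all 10000 random lists. Ppp1r1b was 1.81-fold lower (-0.86 ± 0.04, counting SE), the adenosine receptor Adora2a 1.98-fold lower (-0.99 ± 0.09), the dopamine receptor Drd2 2.27-fold lower (-1.18 ± 0.14) and the enkephalin precursor Penk 1.53-fold lower (-0.61 ± 0.06). Tac1, with 274 and 286 counts, was not called. In the layer 6 and 6b list 5 of 8 genes were called lower and Sla higher, the same counts adjusted over the list alone, with a median of -0.27. The subplate genes Cplx3 (-0.78 ± 0.12) and Ccn2 (-0.50 ± 0.08) had the largest ratios there. The glucocorticoid and stress response list had 6 of 8 genes called lower, also 6 adjusted over the list alone, and a median of -0.28, with Fkbp5 at -0.58 ± 0.06 and Tsc22d3 at -0.47 ± 0.05. Medians below the random range but of at most 0.27 on the log2 scale were found for excitatory neuron (-0.15), microglia (-0.15), hippocampus (-0.14), immediate early (-0.12) and ependymal cell genes (-0.27), the last with none of its 5 tested genes called, also none adjusted over the list alone. The hippocampus list had 4 genes with a positive and 4 with a negative ratio, 1 called higher (Neurod1) and 2 lower, the same adjusted over the list alone. After trends on GC content, length and expression were removed, the excitatory neuron median was -0.06, the astrocyte median -0.06, the striatal median -0.58 and the choroid plexus median 0.78.

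Genes of the choroid plexus, the fibroblasts and blood were higher in replicate 2. All 8 choroid plexus genes had positive log2 ratios and 7 were called in the exact binomial test, 8 adjusted over the list alone. Ttr, the thyroxine and retinol carrier made by the choroid plexus (chromosome 18, 20665280 to 20674321), was at 9.86 TPM in replicate 1 and 131 TPM in replicate 2, with a log2 ratio of normalised counts of 3.58 ± 0.10 (counting SE). Of the 9 meningeal and perivascular fibroblast genes 5 were called higher, also 5 adjusted over the list alone, including Dcn (0.78 ± 0.10), Slc6a13 (0.58 ± 0.12) and Igf2 (0.35 ± 0.04), while Col1a1 was at 0.04 ± 0.04. Of 7 tested erythroid genes 5 were called higher and 1 lower, the same counts adjusted over the list alone, with Hba-a1 at 0.63 ± 0.03 and Hbb-bs at 0.47 ± 0.03. Of 4 tested cerebellum and olfactory bulb genes, Calb2 (0.58 ± 0.09) and Cdhr1 were called higher, the same 2 adjusted over the list alone. Only 2 genes of the hypothalamus and pituitary list had enough counts to be tested. One of them, the vasopressin gene Avp, had 1 count in replicate 1 and 101 in replicate 2.

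The long noncoding and imprinted lists were higher in replicate 2 as well. Of 12 long noncoding RNAs, 8 were called higher and 1 lower in the exact binomial test, 9 and 1 adjusted over the list alone, with a median log2 ratio of 0.32 (SD over genes 0.28) above all 10000 random lists. Malat1 was 1.29-fold higher (0.36 ± 0.004, counting SE), Meg3 1.46-fold (0.54 ± 0.01), Snhg11 1.51-fold (0.59 ± 0.01) and Miat 1.28-fold (0.36 ± 0.02), whereas Pantr1 was lower (-0.29 ± 0.08). Of 20 imprinted genes, 12 were called higher and Snrpn lower, 14 and 1 adjusted over the list alone, with a median of 0.30. Dlk1 rose from 14 to 104 counts (1.99 ± 0.41, a ratio that the added 0.5 CPM understates). Nnat, a regulator of intracellular calcium, was at 0.59 ± 0.03. Meg3 and Kcnq1ot1 belong to both lists, and Igf2 to the imprinted and the fibroblast lists. The structural noncoding list lay just above its random range with a median of -0.005 (-0.006 to 0.05 over the scalings). Annotated retained-intron transcripts took 2.99% of the counts of nuclear protein-coding genes in replicate 1 and 3.68% in replicate 2.

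**Figure D3:**
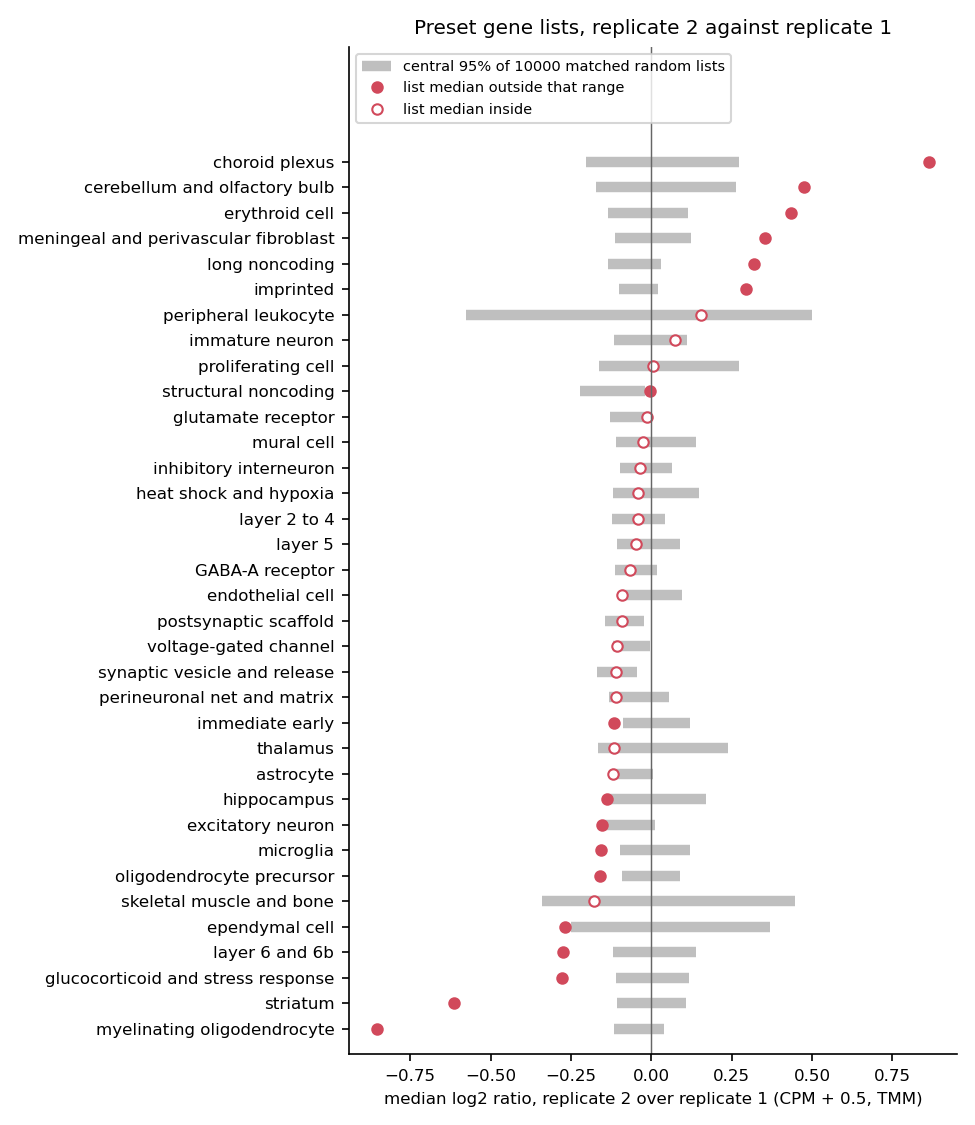
Each point is the median log2 ratio of a preset list, replicate 2 over replicate 1, and grey bars span the central 95% of 10000 random lists matched on expression. Myelinating oligodendrocyte (-0.85) and striatum (-0.61) lie far below their bars, and choroid plexus (0.87) far above.

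Lists of the neuronal machinery stayed within the range of random lists. Medians were -0.11 for synaptic vesicle, -0.09 for postsynaptic scaffold, -0.07 for GABA-A receptor and -0.01 for glutamate receptor genes (-0.02 to 0.04 over the scalings and quantifications), although 10 of 12, 9 of 10, 6 of 10 and 7 of 12 of their genes were called in either direction at these depths (10, 10, 6 and 8 adjusted over the list alone). Of the genes called in these 4 lists, 9, 8, 5 and 4 were lower in replicate 2 and 1, 1, 1 and 3 higher. Astrocyte genes had a median of -0.12 inside the range. In that list 8 of 12 were called lower in the exact binomial test and 2 higher, the same adjusted over the list alone. The gap junction gene Gjb6 had the largest astrocyte ratio (-0.57 ± 0.06, counting SE). In the immature neuron list, Dcx (0.39 ± 0.04) and Sox11 (0.43 ± 0.06) were called higher among 10 genes, with the list median of 0.08 inside its range, and 2 adjusted over the list alone. In the other quantification that median, at 0.11, lay above it.

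Among single genes with 100 or more counts on average, leaving aside Gm49378, the largest ratios towards replicate 2 after Ttr were those of Gm14308 (log2 2.12 ± 0.28, counting SE, but 1.36 in the other quantification, below Gpr101), Gpr101 (1.42 ± 0.17), the semaphorin receptor Nrp2 (1.26 ± 0.06, chromosome 1, 62703285 to 62818695), Baiap3 (1.25 ± 0.11) and Abi3bp (1.20 ± 0.11). Ndst4, the thyrotropin-releasing hormone receptor gene Trhr (1.12 ± 0.16) and Hap1, huntingtin-associated protein (1.06 ± 0.04), followed. Towards replicate 1, leaving aside Gm14288, Gm20388, Gm28539, Zc3h11a and Gm28635, the largest were those of Dennd3 (-2.12 ± 0.11, chromosome 15, 73512560 to 73572242), the sodium channel subunit Scn4b (-1.63 ± 0.06, chromosome 9, 45138395 to 45154152), Pagr1a (-1.22 ± 0.17), Drd2 and the transferrin gene Trf (-1.13 ± 0.06). Gm14288 had 293 counts in replicate 1 and 0 in replicate 2, but a log2 ratio of only -0.25 in the other quantification. Likewise Gm28635 and 1 of the gene entries named Zc3h11a were at -1.41 and -1.43 here but -0.11 and -0.09 there. Gm49378 (1.18 here and 0.93 there), Gm20388 (-1.77 and -2.56) and Gm28539 (-1.73 and -0.81) were called in both quantifications. These, Gm28635 and Zc3h11a overlap other expressed genes on the same strand, so their counts are uncertain, and to a lesser degree those of Nrp2, Hap1, Pagr1a and Trf, which each overlap 1 predicted gene.

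The fifth question was how far a gene's level depends on the quantification, since each library has 1 table made from a transcriptome alignment and another made from the reads directly. Short structural RNAs showed the largest falls, although most genes that differed were higher in the second table. Rn7sk was at 43559 TPM in the first and 1.05 ± 1.48 TPM (SD, n = 2) in the second, Rn7s1 at 130745 and 1.57 ± 0.293 TPM, and Rmrp, at its larger gene entry, at 2881 and 0 TPM. In the other direction Gm28439, beside the mitochondrial-like pseudogenes of chromosome 1, was at 0 in the first table and 373 ± 88.5 TPM in the second, and Gm47283 on chromosome Y at 0 and 167 ± 81.0 TPM. Of 18837 genes at 1 TPM in either, 3211 differed 2-fold or more in the same direction in both libraries, 2621 higher and 590 lower in the second table. Across genes the Spearman rho was 0.903 and 0.899 in the 2 libraries. The median log2 ratio was 0.58 and 0.60, so TPM of the tables are not on 1 scale, and with both rescaled to nuclear protein-coding genes 2058 genes differed, 1367 higher and 691 lower in the second table.

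The last question was which transcript of a gene carried most of its expression. In 8 of 16 preset genes the leading transcript held over 50% of the gene's TPM. App-201 of the amyloid precursor gene held 92.4% ± 0.970 (SD, n = 2), Snap25-201 73.6% ± 1.49, Clta-205 72.3% ± 1.87 and Mapt-204 72.2% ± 0.230. The glycolytic gene Pkm was split between its leading transcripts at 48.9% ± 0.319 and 47.2% ± 0.240, and their order was the other way round in the second table. Mbp-211 held 62.3% ± 4.21 in the first table but 22.6% ± 5.31 in the second, where Mbp-201 led with 27.8% ± 0.0653. Dlg4-203 held 57.8% ± 1.58 and 29.0% ± 0.273 in the tables. For Rbfox3 the libraries differed in which transcript was highest in the first table, while Rbfox3-203 led in both libraries of the second with 40.9% ± 1.27. Over 7843 genes at 10 TPM or more with several transcripts, the libraries shared the leading transcript in 91.9%, and the tables in 76.3% for replicate 1 and 75.7% for replicate 2.

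**Figure D4:**
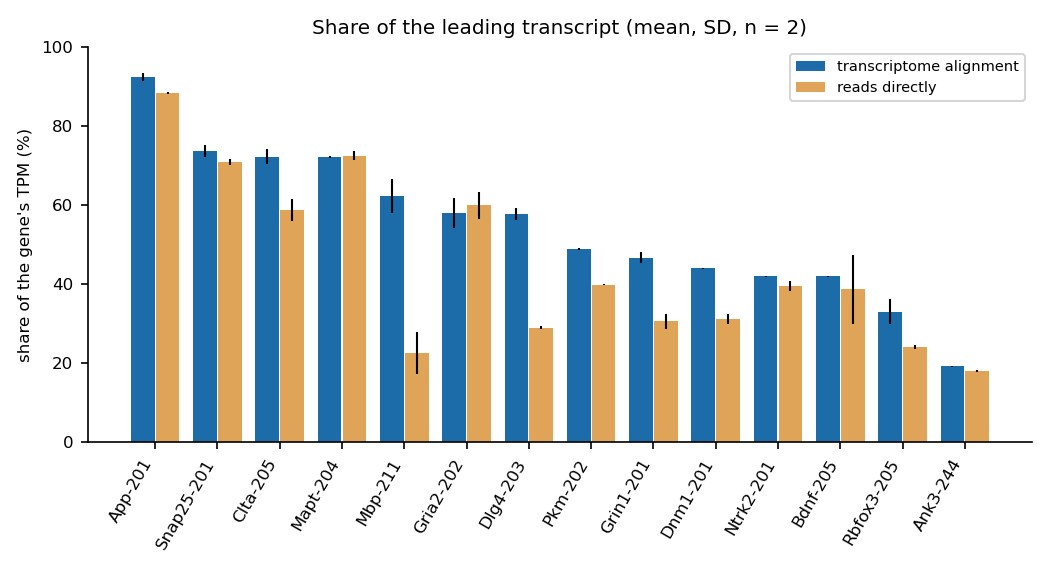
Bars give the share of a gene's TPM held by its leading transcript, as the mean of 2 libraries with SD, in the table from the transcriptome alignment and, for the same transcript, in the table from the reads. App-201 is above 85% in both, and Mbp-211 falls from 62.3% to 22.6%.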

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

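The numbered rows of the gene tables, which name no gene and enter no comparison, were not empty. They held 5 expected counts in replicate 1 and 4.84 in replicate 2, each above the 3 counts that a count of 0 would allow, which is what singled them out. No explanation was weighed for so few counts.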

How the results depend on the processing

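Detected genes numbered 10760 to 16716 over the alternatives, against 14757, and list memberships at 1 TPM or more in both libraries 303 to 316. Median TPM moved in all 37 lists in the other quantification. It moved in 35 with TPM rescaled to nuclear protein-coding genes, since other genes left the total. In the other quantification misc_RNA took 0.00414% of TPM against 30.5%, and protein-coding genes 80.7% against 51.1%. How much of each list's move this accounts for was not tested. Of 26 gene pairs, 24 passed with each pseudocount and 22 in the other quantification, where Kcna2 over Kcna1 and Gfap over Aqp4 no longer passed, and no pair changed sign in either library alone except Mog over Pdgfra, which did not pass. Genes differing between the libraries numbered 3396 to 4108 under other scalings, no count filter and the other quantification, but 182 with a preset dispersion of 0.01, as that test allows for spread beyond counting error. Those at 2-fold or more numbered 96 to 144. Of the 20 named genes, Gm14288, Zc3h11a and Gm28635 were not called in the other quantification; the cause was not tested. Lists outside the random range numbered 17 under DESeq2 size factors and in the other quantification, where immature neuron genes moved outside with a median of 0.11 while structural noncoding genes were not tested. The medians of 8 lists, all near 0, changed sign between scalings or quantifications. The coefficient of variation was 0.0901 in the other quantification. The count of genes 2-fold apart between the tables was 3211, and became 1556 at 5 TPM, 1273 for protein-coding genes and 2058 with both tables rescaled, an alternative chosen after seeing the data; the first 2 test fewer genes. It was 3579 to 4003 in single libraries. Transcript shares above 50% were held by 6 genes in the second table against 8, and 14 of 16 leading shares moved by more than the SD. The spike-in share was 0.720% of TPM against 0.360% of counts, since TPM weights short transcripts more. Leaving out a library ends any comparison between the libraries, and with 2 libraries the value of each lies within 1 SD of the mean by construction. No paired analysis was possible because there is only 1 group. Depth limits the difference between libraries for genes with few counts, such as Aspa and Kcne2.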

Other observations

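Further gene groups were chosen after the data had been examined, before the values of their new members were read. Some members, such as Sst, Npy, Penk and Dnmt3a, also belong to the preset lists or pairs, so this does not hold for them. Among neuropeptides, Cck, the peptide of many cortical neurons, was highest at 306 ± 14.9 TPM (SD, n = 2), above Sst and Npy (87.9 ± 5.16 TPM), while Crh (5.64 ± 1.11 TPM) and Nts (4.81 ± 1.53 TPM) were low. Secreted and metal-binding proteins of glia were among the most abundant messengers of the tissue, with Cst3 at 1032 ± 32.1 TPM, the lipid carrier Apoe at 969 ± 6.31 TPM and Sparcl1 at 642 ± 32.9 TPM. In that group 8 of 9 genes were called lower in replicate 2 by the exact binomial test, also 8 adjusted over the list alone, most of all the metallothioneins Mt2 (log2 -0.63 ± 0.06, counting SE) and Mt1 (-0.43 ± 0.05), with Apoe at -0.08 ± 0.01. Its median of -0.15 lay at percentile 0.95 of matched random lists, outside their central 95%. Cholesterol synthesis genes, which oligodendrocytes use heavily, did not follow the myelin genes: their median log2 ratio was -0.07 (SD over 12 genes 0.08), at percentile 17.6 of matched random lists, with 4 of 12 called lower and none higher, also 4 adjusted over the list alone.

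Thyroid hormone genes were expressed with the receptor Thra at 463 ± 17.0 TPM (SD, n = 2) and Thrb at 28.5 ± 0.0636 TPM. The activating enzyme Dio2 was at 40.9 ± 0.247 TPM. The target Klf9 was lower in replicate 2 (log2 -0.37 ± 0.02, counting SE). Of the 8 genes of this group 4 were called lower and 1 higher in the exact binomial test, 5 and 1 adjusted over the list alone, and the median of -0.13 lay at percentile 1.82, also outside. Of trophic factor genes, the receptors Ntrk2 (159 ± 0.969 TPM) and Ntrk3 (63.0 ± 2.54 TPM) were far above their ligands Bdnf (8.45 ± 0.403 TPM) and Ntf3 (1.73 ± 0.431 TPM). Ngfr and Igf1 were called higher and Ntrk2 and Igf1r lower among 10 genes, the same numbers adjusted over the list alone. Among chromatin genes, Dnmt3a stood at 163 ± 4.64 TPM and Dnmt3b at 0.550 ± 0.113 TPM, with 2 of 10 genes called lower and 1 higher, the same adjusted over the list alone.

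In the patterns below, the tests of normalisation and of the assumed fragment length were chosen after the results they measure had been seen. Myelin and striatal genes were lower in replicate 2. After removing trends on GC content, length and expression, the median log2 ratio of the myelin list was -0.81 (SD over genes 0.16). This argues against these trends as the whole cause. Under the scaling that brought it closest to 0, the median was -0.80. The log2 factor between libraries was 0 with total counts and 0.06 with DESeq2 size factors, the same for all genes. That test could not have ended otherwise, and shows only that the choice among these scalings matters little here. Less striatum and adjoining white matter in the dissected piece is a candidate explanation. In a second list of striatal genes, fixed before their values were seen, 12 of 14 tested genes were lower, with a median of -0.40 below all 10000 random lists. That list repeats the pattern in further genes of the same libraries. Any cause of lower striatal RNA would lower it, so it cannot single out the dissection. Isl1 went the other way at 1.06, as did the choroid plexus and Avp, so a lower share of all tissue beneath the cortex is not what these values show. A difference in maturity between the mice, all labelled 14 days, remains open and was not tested.

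Nuclear long noncoding RNAs were higher in replicate 2. After the same correction for GC content, length and expression, the median log2 ratio of the list was 0.28 (SD over genes 0.29). This argues against these trends as the whole cause. Under the scaling that brought it closest to 0 the median was 0.32, but the scalings differ too little for that test to have ended otherwise. More nuclear or unspliced RNA in replicate 2 may account for the higher long noncoding RNAs. The share of a gene's counts in its retained-intron transcripts was higher there by a median log2 ratio of 0.26 over 3428 genes. The bootstrap interval over genes was 0.24 to 0.28, and the share was higher in 78.9% of them. That interval covers the spread over genes, which are not independent, and not how far libraries of the same tissue vary. The second table gave a median of 0.23 over 3557 genes. Small RNAs of the nucleus did not rise together. The snRNA class took 0.106% of gene counts in replicate 1 and 0.0958% in replicate 2. The snoRNA class took 0.0368% and 0.0333%. The scaRNA class, at 0.0206% and 0.0218%, and Rmrp, with 10616 and 11386 counts at its larger gene entry, went the other way. Rn7sk had 212575 and 211769 counts but 42697 and 44421 TPM, so its direction depends on the scale. A rise of all nuclear RNA is therefore not what these values show. Reads from genomic DNA could act like unspliced RNA and were not tested, and a biological difference between the mice remains open.

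Short transcripts were missing from the quantification made from the reads. Of genes with 100 or more counts in the first table whose longest transcript was shorter than the gap between length and effective length, 100% of 80 genes in replicate 1 and 98.7% of 75 in replicate 2 kept under 5% of their counts, against 0.211% and 0.201% of genes longer than 2 times that gap. This fits an assumed fragment longer than the transcript, a technical source. Reads shared between identical copies do not explain it, since the 46 short genes with a sequence of their own kept a median of 0% of their counts, as did the 23 with a copy. No biological explanation was tested.

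Y-linked genes were not at 0 in the second table, where Kdm5d was at 0.821 ± 0.0654 TPM (SD, n = 2) in these females and Uty higher. All genes of chromosome Y together were at 136 and 258 TPM there, most of it in Gm47283. In the first table they were at 1.65 and 1.28 TPM. Whether the reads given to Gm47283 come from chromosome Y or from similar sequence elsewhere was not tested. In the second myelin list, fixed with the second striatal list, 10 of 11 tested genes were called lower in replicate 2 by the exact binomial test, also 10 adjusted over the list alone, and Car2 was at -0.06.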
